A study of Homo sapiens with 4 samples.

How the data were processed

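Gene expression was measured by RNA sequencing of total RNA from cultured MDA-MB-231 cells, with library preparation and Illumina sequencing done by a service company, per the labels' protocols. The 4 libraries were grouped by their titles, 2 as WT and 2 as KO, and are named by group and replicate number. The submitters' processing notes name STAR, Subread and DESeq2 with no version, role or settings. The genome build, annotation and strand setting are not given in the sources used here.

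The authors deposited 1 table of FPKM values (fragments per kilobase of gene length and per 1000000 assigned fragments), with 39259 genes by Entrez ID, their exon coordinates and their length in base pairs, per the file headers. The layout of its columns is that of featureCounts, a program of Subread. From the values, FPKM times length in kilobases summed to 1000000 in every library, so the scaling was to all fragments assigned to genes. Dividing these products by the smallest one above 0 gave whole numbers for 100% of the values above 0 in each library (tolerance 0.001). The fragments behind the values were computed back in this way and gave the depths. Counting the table's columns found 0 that belong to other samples. Gene symbols came from a RefSeq gene table on GRCh38.p14, matched by Entrez ID for 37708 genes (96.0%). Of 37671 matched genes with all exons on 1 chromosome, 98.4% had a start or an end within 1000 bp of that assembly, and coordinates are printed as deposited.

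Choices for the main comparison were made before the data were examined. Because the table holds FPKM and not counts, the main test was limma (version 3.58.1, R 4.3.3; lmFit and eBayes with trend and robust) on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 4 libraries (11716 genes), libraries labelled KO minus WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. A count-based test had been planned only for a table of counts and was not used as the main result. Fold changes on this scale understate the change of genes with low values, so FPKM means with SD (n = 2) are given beside them. In fits without 1 library, the lone library of its group was assumed to vary like the pair of the other group. Gene lists, 45 in all, were fixed beforehand, and the 41 with at least 5 tested members were tested with camera (preset correlation 0.01) and adjusted over the lists, with camera with an estimated correlation and fry beside it. Fry tests whether the genes of a list move, on balance, one way, and does not compare a list with other genes. Counts of members are given over all genes tested and adjusted over the list alone.

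Genes were named by a fixed rule: RIOX2 and RIOX1; the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 1 FPKM in the higher group, no overlap between the groups and a protein-coding symbol, read as the RefSeq class protein-coding (LOC, LINC, MIR, SNOR, RNU, antisense, divergent, intronic, dotted, Y-linked and X-inactivation genes left out). From each called list, or list with at least 5 members past the threshold, the rule took the 3 members with the largest change in the main direction and 1 in the other. It also took up to 6 members past the threshold from each of the lists of histone demethylases and methyltransferases. The rule gave 166 genes, not all of which are described, and names chosen after the values were seen are marked as such in the closing section. The regional medians given beside genes leave out the gene itself and are those of its 20 Mb bin. Where the genes of a bin moved both ways, its median need not describe those nearest to the named gene.

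Within groups the libraries differed by more than counting noise (chi-square per degree of freedom 8.23 for the WT pair and 5.69 for the KO pair, against 55.1 to 73.8 across groups), so all 4 were kept as separate libraries. The labels number the replicates of both groups 1 and 2 and name no shared culture or day, so the numbers were not treated as pairs. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, quantile normalization, limma without trend or robust, a replicate block and each library left out in turn. Alternatives added after the data were seen were voom on the computed fragments, median-of-ratios scaling, FPKM without mitochondrial genes, fragments thinned to the shallowest library, bin medians subtracted, trends with length and GC content removed (splines with 5 degrees of freedom) and a crossed replicate block. GC content came from the longest GENCODE 29 transcript and was known for 97.0% of the tested genes.

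The steps were tested on simulated data drawn from the libraries' own means and depths, with 11705 genes tested. In 1 draw, 200 genes with a mean of at least 1 FPKM in the data were changed, and a list of 43 others was lowered by 0.2 (log2). The rates below cover those of the 200 that passed the filter in the simulated data. The simulation used 1 dispersion for all genes and changed a far smaller share of genes than was called in the data. Its rates therefore need not hold for the data. The fit recovered 74.0% of genes changed by 1.25-fold, 91.7% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold in the right direction. Of its calls, 11.7% were unchanged genes, more than the nominal 5%, and with no gene changed it called 16 of 11714. The lowered list was called, together with 2 others, of which one shared 9 members with it and the other 0. Intervals cover counting error only, and the fragments carry no known molecular identifiers.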

Results

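RNA from MDA-MB-231 cells, an established human cell line of triple-negative breast cancer, was sequenced in 4 libraries. In 2 libraries the cells were wild type (WT), and the other 2 are labelled as a knockout (KO) of mdig, also called MINA53. This protein is a JmjC-domain oxygenase encoded by RIOX2, and it has been studied for its roles in ribosome production, histone methylation and the growth of cancer cells. The design asks which transcripts differ between the WT cells and those labelled KO. The fragments assigned to genes numbered 45173267 in WT replicate 1, 22503981 in WT replicate 2, 48768932 in KO replicate 1 and 52163811 in KO replicate 2. WT replicate 2 was therefore the shallowest library, and there 3 fragments on a gene of 1 kb correspond to 0.133 FPKM, against 0.0575 to 0.0664 FPKM in the other libraries. Mitochondrial transcripts took 7.0% and 7.91% of the fragments in the WT libraries and 7.42% and 6.54% in the libraries labelled KO. Nothing in the labels says that the replicates were separate cultures or clones, so the p-values measure only the spread between these libraries, which may be technical.

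RIOX2, the gene that the labels name as knocked out (Entrez ID 84864, chromosome 3, 97941818 to 97972431, coordinates as deposited, which match GRCh38), was examined first. Its transcript was not lower in the libraries labelled KO. It measured 8.60 and 8.24 FPKM in WT replicates 1 and 2 and 9.23 and 9.82 FPKM in KO replicates 1 and 2, from 1174 to 3243 fragments per library. The log2 change was 0.16 (SE 0.060) and did not pass the threshold (limma, adjusted p = 0.0546). Other settings put it past the threshold, always as a rise: it was 0.19 without WT replicate 1 (adjusted p = 0.0131) and 0.24 on fragment counts with voom (adjusted p = 0.00554), and over all settings the adjusted p ranged from 0.00554 to 0.360. The table holds 1 value per gene and none per exon, so it does not show whether a part of the transcript was lost, and a small edit can leave the level of an RNA as it was. The RNA level of RIOX2 thus left the label of both KO libraries unchecked, and every direction below is between the libraries labelled KO and the WT libraries. Its paralog RIOX1, also a ribosomal oxygenase, measured 8.10 ± 0.416 FPKM in WT and 7.26 ± 0.163 FPKM in the libraries labelled KO (mean ± SD, n = 2 libraries, as in all such pairs of values here), with a log2 change of −0.14 and an adjusted p of 0.0882. It passed the threshold as a fall without WT replicate 1 (−0.19, adjusted p = 0.0140) and with bin medians subtracted (−0.22, adjusted p = 0.0225), and over all alternatives the adjusted p ranged from 0.0140 to 0.376.

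Widespread differences separated the libraries labelled KO from WT. Of 11716 genes tested, 2527 were higher and 3323 were lower in the libraries labelled KO (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05), which is 49.9% of the genes. On this scale 86 genes rose and 65 fell by at least 2-fold, against 149 and 154 with a pseudocount of 0.1, 209 and 142 with voom on fragment counts and 50 and 29 with a mean of at least 5 FPKM. The first principal component held 86.8% of the variance and parted the groups. Pearson's r across genes, which are not independent replicates, was 0.996 between the WT libraries, 0.998 between the libraries labelled KO and 0.975 to 0.980 between groups. The counts depended on the libraries kept: they fell without either KO library and rose without either WT library. In these fits the spread within groups came from the complete pair alone. None of the main calls still tested changed sign in them. The balance of directions depended on the scaling, since 43.2% of the called genes were higher with FPKM as deposited, 55.3% after median-of-ratios scaling and 55.1% with voom on fragment counts.

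**Figure D1:**
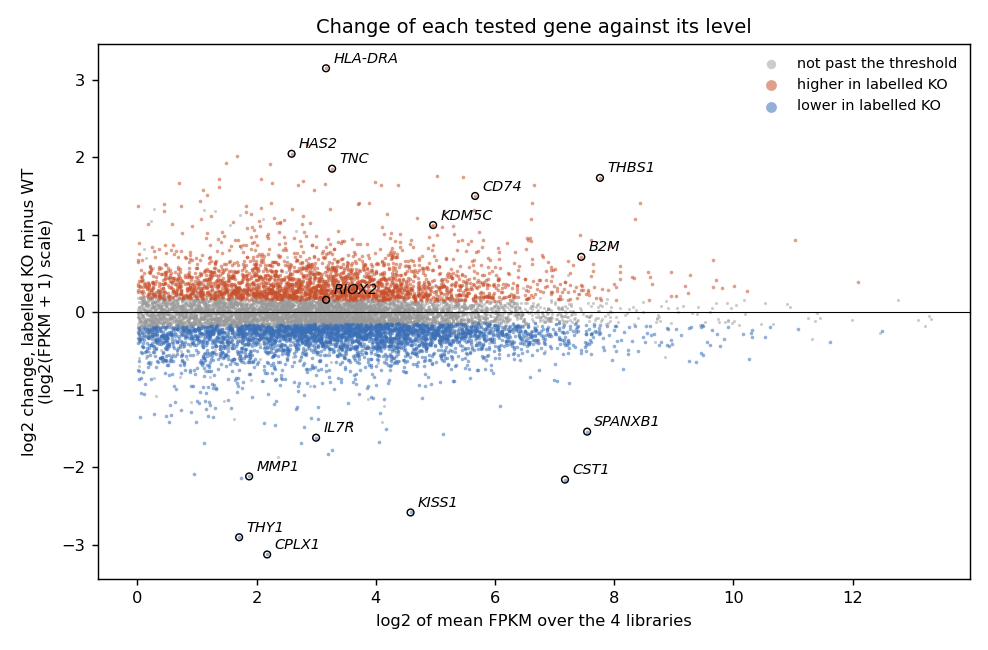
Each point is 1 of the 11716 tested genes, with the log2 of its mean FPKM over the 4 libraries on the x axis and its log2 change (libraries labelled KO minus WT, log2(FPKM + 1) scale) on the y axis; orange and blue mark genes past the adjusted p threshold. The 2527 higher and 3323 lower genes lie on both sides of 0, with HLA-DRA at 3.15 and CPLX1 at −3.13 as the extremes, while RIOX2 lies at 0.16.

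The 12 largest rises ranged from 1.71 to 3.15 on the log2 scale. HLA-DRA, the alpha chain of an MHC class II molecule, rose from 1.03 ± 0.340 to 16.9 ± 0.206 FPKM (log2 change 3.15, SE 0.11, adjusted p = 1.06e-05). HLA-DRB1, a beta chain that pairs with it, rose by 2.01 on the log2 scale, though its reads can be shared with other HLA-DRB genes. HAS2, which makes hyaluronan, rose from 1.74 ± 0.232 to 10.3 ± 0.536 FPKM (2.05, SE 0.075). The matrix glycoproteins TNC (tenascin-C, 3.61 ± 0.291 to 15.6 ± 0.142 FPKM) and THBS1 (thrombospondin-1, 100 ± 17.1 to 333 ± 7.35 FPKM) rose by 1.85 and 1.73. PMEPA1, a TGF-beta-induced inhibitor of that pathway, rose by 1.75 (14.4 ± 0.336 to 50.9 ± 0.268 FPKM), as did the calcium-binding protein S100A2 (1.75). TNFSF10, which encodes the death ligand TRAIL, rose by 1.72, and LYPD6B by 1.92. TRIML2 rose by 2.18 (1.98 ± 0.0481 to 12.5 ± 0.443 FPKM); it lies on the long arm of chromosome 4, where the other genes of its 20 Mb bin had a median change of 0.40. ANXA8L1 and ANXA8, near-identical copies whose reads cannot be told apart with certainty, rose by 1.93 and 1.71 in a bin with a median of 0.29.

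Among the falls, CPLX1, a regulator of synaptic vesicle fusion, went from 8.91 ± 0.889 to 0.136 ± 0.154 FPKM (log2 change −3.13, SE 0.11, adjusted p = 5.06e-06). This rested on 3 and 29 fragments in KO replicates 1 and 2, and the gene lies at the end of the short arm of chromosome 4, in a bin with a median change of −0.40. THY1, the surface glycoprotein CD90, fell by 2.91 on the log2 scale. It had 2519 fragments in the WT libraries together and 2 in the libraries labelled KO, a ratio of 1878 after division by the assigned fragments (95% exact interval 519 to 15519, counting error only). KISS1, the precursor of the metastasis-suppressing peptide kisspeptin, fell from 41.8 ± 4.94 to 6.12 ± 0.409 FPKM (−2.59, SE 0.087). The neuropeptide gene GAL (−2.14) and the collagenase gene MMP1 (−2.12, from 6.59 ± 0.357 to 0.746 ± 0.114 FPKM) also fell. So did the cytokine IL24 (−1.69) and the interleukin-7 receptor IL7R (−1.62, from 12.6 ± 0.727 to 3.41 ± 0.226 FPKM). The cystatins CST1 (−2.16, from 237 ± 6.16 to 52.1 ± 0.570 FPKM) and CST2 (−1.68) are similar enough in sequence to share reads, and so is SPANXB1 (−1.54, from 279 ± 13.4 to 95 ± 0.625 FPKM) with other SPANX genes. SHISA3, which restrains WNT and FGF signaling, fell by 1.83, and COX7B2, a subunit of cytochrome c oxidase, fell by 1.48.

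**Figure D2:**
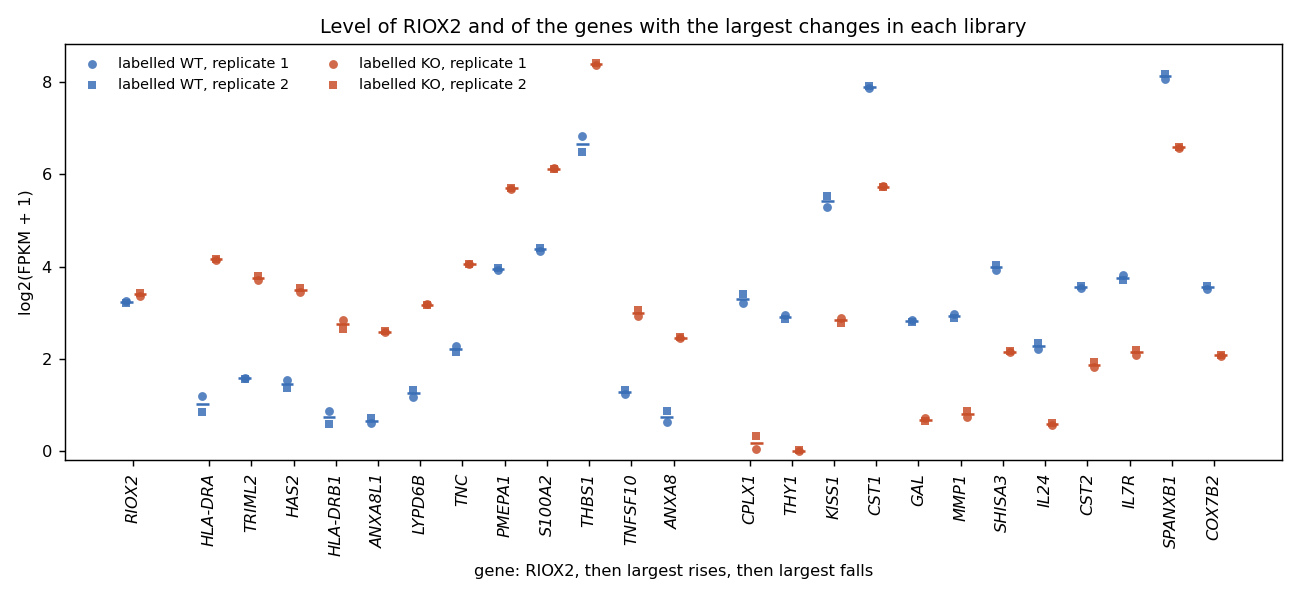
Level of each gene in each library as log2(FPKM + 1), with WT libraries in blue, libraries labelled KO in orange, circles for replicate 1, squares for replicate 2 and a bar at the mean of each group (n = 2). RIOX2 is close in the 2 groups (8.60 and 8.24 against 9.23 and 9.82 FPKM), whereas for the 12 largest rises and the 12 largest falls the groups are apart, with HLA-DRA rising to 16.9 FPKM and THY1 falling to 0.00340 FPKM on average.

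Genes of MHC class II presentation rose: all 6 tested members of the list were higher (6 rose and 0 fell adjusted over the list alone), with a median log2 change of 1.37. Of its 14 members, 3 had a mean of at least 1 FPKM in WT and 7 in the libraries labelled KO, so the filter kept some through their level in the latter, and with no filter the median was 0.67. Besides HLA-DRA and HLA-DRB1, CD74, the invariant chain that guides class II molecules, rose from 26.0 ± 1.35 to 75.5 ± 2.24 FPKM. In the MHC class I list, 15 of 19 tested members rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.40. HLA-B rose from 64.1 ± 0.0585 to 123 ± 1.51 FPKM (0.93), the immunoproteasome subunit PSMB9 by 0.68, and B2M, the light chain of class I molecules, from 132 ± 0.0383 to 217 ± 3.85 FPKM (0.71). B2M lies on chromosome 15 in a bin with a median of 0.36. TAP2, a subunit of the peptide transporter, was the member that fell, by 0.24, a call lost without KO replicate 1 (−0.21, adjusted p = 0.106) or KO replicate 2 (−0.26, adjusted p = 0.0564). HLA genes vary in sequence between people, so reads of these genes can be lost or shared. Both lists differed from other genes in camera with a preset correlation (adjusted p = 3.37e-05 for class II and 1.17e-06 for class I). With an estimated correlation, none of the 41 tested lists was called, and 1 list had an unadjusted p under 0.05. This test had few degrees of freedom with 2 libraries per group. Calls were also lost where the estimated correlation lay below the preset 0.01, as for class II (−0.158, unadjusted camera p = 0.0390) and glycolysis and hypoxia (9.5e-06, unadjusted camera p = 0.0982). The missing calls thus do not by themselves show that correlation between genes made the calls with the preset. For other called lists the estimate lay well above the preset. It was 0.406 for cytosolic ribosomal proteins, 0.258 for oxidative phosphorylation and 0.179 for JmjC oxygenases and histone lysine demethylases. For lists like these, correlation between genes may have contributed to the calls with the preset. Fry called 20 lists, among them 13 of the 16 called with the preset correlation and also collagens (adjusted p = 0.0104) and mesenchymal genes (0.0302). It did not call cytosolic ribosomal proteins (0.0964), oxidative phosphorylation (0.0851) or JmjC oxygenases and histone lysine demethylases (0.0561). For both MHC lists the adjusted p was 0.513 with an estimated correlation.

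In the list of interferon-stimulated genes, 17 of 37 tested members rose and 6 fell (17 and 6 adjusted over the list alone; median 0.17, camera adjusted p = 0.00773; adjusted p = 0.610 with an estimated correlation). SAMD9L, an antiviral factor, rose from 1.96 ± 0.0498 to 6.50 ± 0.144 FPKM, and the guanylate-binding protein GBP1 from 9.04 ± 0.604 to 17.5 ± 1.14 FPKM. DDX60 rose by 0.93 in a chromosome 4 bin with a median of 0.54. RIGI, a sensor of viral RNA, fell by 0.46. With a mean of at least 5 FPKM as the filter, this list was no longer called (median 0.041, adjusted p = 0.135). The list of inflammatory cytokines and NF-kB targets went both ways, with 8 of 24 members higher and 9 lower (9 and 9 adjusted over the list alone; camera adjusted p = 0.801). There IL6 rose from 2.85 ± 0.177 to 5.09 ± 0.193 FPKM, while the adhesion molecule ICAM1 fell from 36.4 ± 0.0272 to 20.5 ± 0.265 FPKM along with IL7R and IL24. Its median was 0.057 and its mean −0.10, so these differ in sign, and its direction in camera was up. Of 16 genes listed as T helper cytokines, a group in which mdig has been studied, 1 was tested. This gene, IL12A, measured 1.13 FPKM in WT and 0.934 FPKM in the libraries labelled KO, with 0 called. It does not stand for the group, about which nothing can be said here.

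Matrix genes past the filter rose more often than they fell. Of 18 tested matrix glycoproteins and proteoglycans, 13 rose and 2 fell (13 and 3 adjusted over the list alone; median 0.42, camera adjusted p = 0.000206; adjusted p = 0.529 with an estimated correlation). Besides TNC, the proteoglycan SPOCK1 rose from 0.297 ± 0.00248 to 2.43 ± 0.00210 FPKM and LTBP2, a protein of elastic fibers, by 1.04. The laminin chain LAMA5 fell by 0.34; it lies at the end of chromosome 20, where its bin had a median of −0.39. Among matrix proteases and their inhibitors, 9 of 19 rose and 2 fell (9 and 3 adjusted over the list alone; median 0.15, camera adjusted p = 0.0237; adjusted p = 0.513 with an estimated correlation). The urokinase gene PLAU rose from 58.4 ± 1.32 to 136 ± 0.105 FPKM in a chromosome 10 bin with a median of 0.35, the protease inhibitor TIMP3 rose from 114 ± 7.37 to 228 ± 4.37 FPKM, and the membrane-bound protease MMP14 rose by 0.92, against the fall of MMP1. With no filter on low values, neither of these lists was called (adjusted p = 0.0794 and 0.147), and their medians were 0.0032 and 0.0036. Collagens counted 7 higher and 3 lower of 16 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0562). Of these, COL5A1 (1.64), COL6A3 (1.37) and COL7A1 (1.27) rose most and COL27A1 fell by 0.46. Integrins counted 7 higher and 1 lower of 12 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0519). ITGB1, the shared beta-1 subunit, rose from 134 ± 23.3 to 256 ± 11.2 FPKM, and ITGB2, a beta subunit typical of leukocytes, fell from 11.8 ± 0.238 to 4.48 ± 0.0941 FPKM.

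Targets of TGF-beta changed in both directions, with 13 of 22 tested members higher and 7 lower (13 and 7 adjusted over the list alone; median 0.22, camera adjusted p = 0.0166; adjusted p = 0.513 with an estimated correlation). Of the 27 members of this list, 26 were analysed here and 22 passed the filter. TGFBI, an adhesion protein of the matrix, rose from 52.9 ± 2.29 to 143 ± 3.48 FPKM together with PMEPA1 and THBS1, and the activin antagonist FST fell by 0.60. With no filter on low values the list was not called (adjusted p = 0.0839). Epithelial genes rose more often than they fell, with 11 of 19 higher and 3 lower (12 and 4 adjusted over the list alone; median 0.23, camera adjusted p = 0.00829; adjusted p = 0.529 with an estimated correlation). The protease inhibitors SPINT2 (65.2 ± 5.63 to 127 ± 1.56 FPKM) and SPINT1 (2.78 ± 0.157 to 6.34 ± 0.114 FPKM, bin median 0.36) each rose by 0.96, and the tight-junction gene CLDN1 fell by 0.75. Of 23 mesenchymal genes, 10 rose and 8 fell (10 and 8 adjusted over the list alone; camera adjusted p = 0.433). Their median was −0.058 and their mean 0.23, since S100A4 (196 ± 6.56 to 452 ± 11.6 FPKM), THBS1 and TGFBI rose far more than CALD1 fell (−0.47). This list shared 4 tested members with the TGF-beta list.

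Ribosome-related genes were lower in the libraries labelled KO. Of 43 genes for ribosome biogenesis and RNA polymerase I, 27 fell and 1 rose (28 and 1 adjusted over the list alone; median −0.22, camera adjusted p = 8.54e-05; adjusted p = 0.529 with an estimated correlation). BOP1, needed to process the large-subunit ribosomal RNA, fell from 65.1 ± 4.64 to 38.4 ± 2.48 FPKM (−0.75, bin median −0.27), and RRP9, a small nucleolar RNP component, by 0.62 (bin median −0.21). NOP14, a small-subunit processing factor, fell by 0.68 in the shifted bin of chromosome 4 (−0.40), and GAR1 rose by 0.32 on the long arm of that chromosome (bin median 0.53); the bin median of GAR1 exceeded its own rise. Of 77 cytosolic ribosomal proteins, 40 fell and 7 rose (42 and 8 adjusted over the list alone; median −0.18, camera adjusted p = 0.00773; adjusted p = 0.753 with an estimated correlation). RPL38 (353 ± 40.1 to 211 ± 2.60 FPKM), RPS15 (805 ± 96.5 to 515 ± 53 FPKM) and RPL35A (−0.62) fell most. Ribosomal protein genes have many pseudogene copies that can take reads. Their share of all fragments was 4.70% and 5.01% in WT and 4.39% and 4.38% in the libraries labelled KO. This call was lost without WT replicate 2 (median −0.13, adjusted p = 0.0660) and after the trends with gene length and GC content were removed (median −0.065, adjusted p = 0.175).

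Of 29 MYC targets, 20 fell and 2 rose (20 and 2 adjusted over the list alone; median −0.29, camera adjusted p = 0.000920; adjusted p = 0.513 with an estimated correlation). The list shared 9 tested members with that for ribosome biogenesis. The co-chaperone FKBP4 fell from 52.1 ± 1.17 to 27.6 ± 0.125 FPKM, the mitochondrial chaperonin HSPE1 by 0.78 and ODC1, which starts polyamine synthesis, by 0.68, whereas the cap-binding factor EIF4E rose by 0.51 on chromosome 4 (bin median 0.27). The bin of EIF4E held 23 genes higher and 13 lower, so its median need not describe the nearest genes. Of 42 nuclear genes of oxidative phosphorylation, 22 fell and 1 rose (22 and 1 adjusted over the list alone; median −0.17, camera adjusted p = 0.0115; adjusted p = 0.732 with an estimated correlation). The ATP synthase subunit ATP5F1C fell from 206 ± 6.31 to 143 ± 4.14 FPKM (bin median −0.32), cytochrome c1 (CYC1) fell by 0.52 (bin median −0.27), and NDUFA1 of complex I rose by 0.71 on the X chromosome (bin median 0.36). This call too was lost without WT replicate 2 (median −0.15, adjusted p = 0.0857) and with length and GC trends removed (median −0.099, adjusted p = 0.0558). Of the 15 mitochondrially encoded genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.343).

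Among antioxidant targets of NRF2, 13 of 24 rose and 5 fell (13 and 5 adjusted over the list alone; median 0.24, camera adjusted p = 0.00773; adjusted p = 0.513 with an estimated correlation). The export pump ABCC3 rose from 6.70 ± 0.0530 to 19.5 ± 0.209 FPKM, the quinone reductase NQO1 from 19.9 ± 0.658 to 39.8 ± 1.46 FPKM, and the cystine transporter SLC7A11 by 0.82 on chromosome 4 (bin median 0.48), while glutathione reductase (GSR) fell by 0.46. Targets of hypoxia and glycolysis counted 14 higher and 6 lower of 34 (14 and 7 adjusted over the list alone; median 0.10, camera adjusted p = 0.0286; adjusted p = 0.513 with an estimated correlation). VEGFA rose from 34.3 ± 0.155 to 71.4 ± 0.770 FPKM and the collagen prolyl hydroxylase P4HA1 by 0.87 (bin median 0.35), while the vasodilator peptide gene ADM fell by 0.94. In cholesterol synthesis and uptake, 10 of 25 rose and 4 fell (11 and 4 adjusted over the list alone; median 0.13, camera adjusted p = 0.0237; adjusted p = 0.513 with an estimated correlation). The sterol oxidase MSMO1 rose from 13.5 ± 0.497 to 26.5 ± 0.553 FPKM in a chromosome 4 bin with a median of 0.54, and INSIG1, which retains the sterol sensor in the endoplasmic reticulum, rose by 0.79.

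Because mdig is a JmjC protein studied for its effect on histone methylation, genes of these enzymes were examined as a group. Of 26 tested JmjC oxygenases and histone lysine demethylases, 8 rose and 5 fell (8 and 5 adjusted over the list alone; median 0.13, camera adjusted p = 0.0465; adjusted p = 0.732 with an estimated correlation). KDM5C, an X-linked demethylase of histone H3 lysine 4, rose from 19.2 ± 0.518 to 43.1 ± 0.970 FPKM (1.12, SE 0.054), in a bin with a median of 0.055. PHF8, in the same bin of the X chromosome, rose by 0.71 and KDM5B by 0.55, and JMJD8 fell by 0.44. KDM5C and PHF8 are close to each other, starting at 53176277 and 53936680. The genes of their bin went both ways (quartiles −0.13 and 0.36, 30 higher and 12 lower). Its median thus does not exclude a shift of a smaller region that holds both, which was not tested. JMJD1C (0.54), JMJD7 (0.48) and KDM4A (0.47) rose in bins with medians of 0.35, 0.36 and 0.23, and reads of JMJD7 can also come from a readthrough transcript. The call of this list was lost under 6 alternatives. They include median-of-ratios scaling (median 0.18, camera adjusted p = 0.0642), where the median was not smaller, and the fit without WT replicate 2, where it was 0.056. Of 25 tested histone methyltransferases and their partners, 3 rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.863). NSD2 (−0.40) and SUV39H2 (−0.39) fell in bins with medians of −0.40 and −0.32, SMYD2 fell by 0.27, and RBBP4 rose by 0.32 (bin median 0.24). With bin medians subtracted, the calls of JMJD1C (0.19), JMJD7 (0.12), NSD2 (0.00027), SUV39H2 (−0.073) and RBBP4 (0.081) were lost. TRIM28, a corepressor that recruits H3K9 methyltransferases, fell by 0.27, and NSD3 rose by 0.27. Without KO replicate 2 the calls of SMYD2 (−0.25, adjusted p = 0.0729), TRIM28 (−0.23, adjusted p = 0.0661) and NSD3 (0.22, adjusted p = 0.134) were lost. All 6 tested HOX genes fell (0 rose and 6 fell adjusted over the list alone; median −0.42, camera adjusted p = 0.0237; adjusted p = 0.513 with an estimated correlation). HOXB6 fell from 1.85 ± 0.125 to 0.862 ± 0.0978 FPKM and HOXC8 from 1.38 ± 0.133 to 0.744 ± 0.0689 FPKM, both low levels. The median of this list was −0.43 without WT replicate 1 and −0.29 without WT replicate 2, and the list was not called in either fit. It was also not called with no filter on low values (median −0.089, camera adjusted p = 0.150) or with length and GC trends removed (median −0.34, camera adjusted p = 0.0548). Of all HOX genes, 7 had a mean of at least 1 FPKM in WT and 4 in the libraries labelled KO, so the filter kept some through their WT level.

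**Figure D3:**
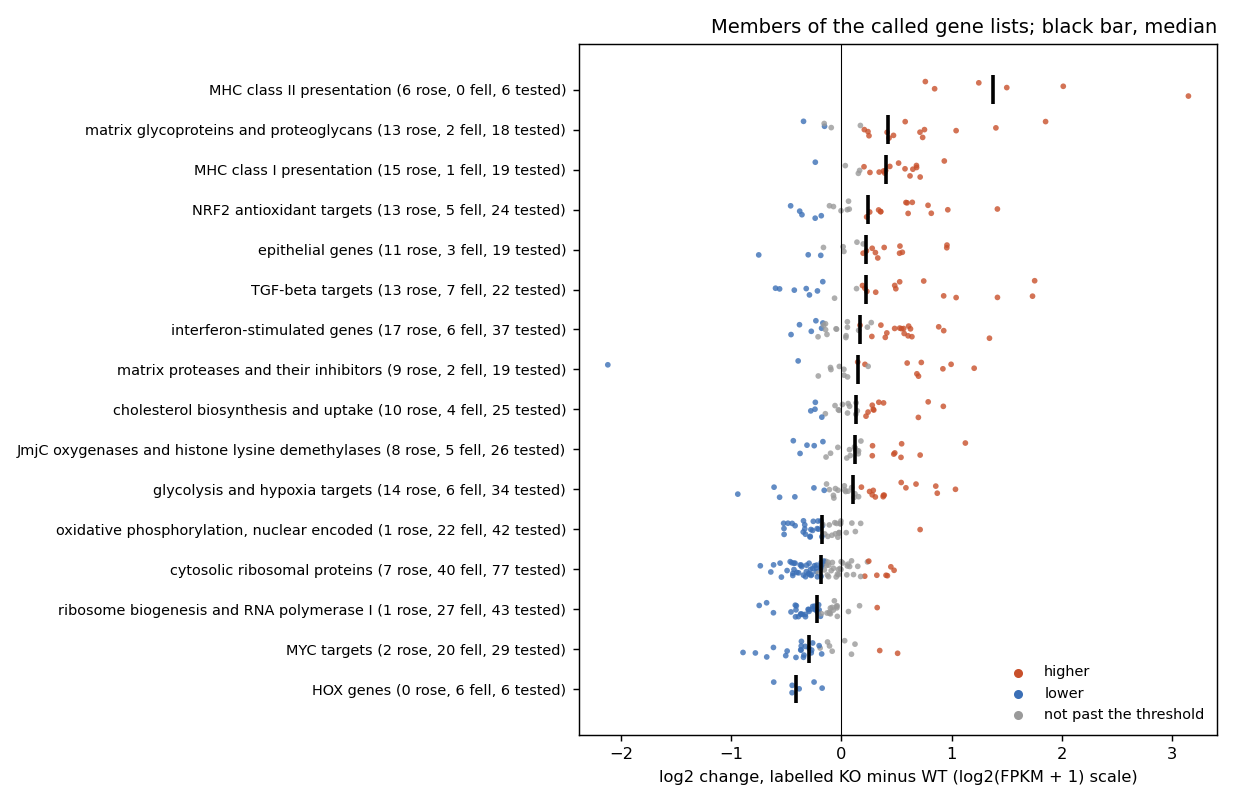
Log2 change (libraries labelled KO minus WT, log2(FPKM + 1) scale) of every tested member of the 16 lists called by camera with the preset correlation; each point is a gene, orange and blue mark members past the threshold, grey marks the others, and the black bar is the median. Medians run from −0.42 for HOX genes to 1.37 for MHC class II presentation, and most lists hold members on both sides of 0.

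Neighboring genes moved together. In 151 bins of 20 Mb with at least 20 tested genes each, the SD of the bin medians was 0.17 between the libraries labelled KO and WT, against 0.033 between the WT libraries and 0.024 between the libraries labelled KO. The median of 15 bins lay more than 0.3 from the median of all genes (−0.041), 13 of them higher and 2 lower, and these bins held 760 tested genes and 11% of all called genes. The first 20 Mb of chromosome 4 had a median of −0.40, with 53 genes lower and 15 higher, whereas from 100 to 120 Mb on that chromosome the median was 0.53, with 49 of 52 genes higher and 0 lower. Medians of 0.37 on chromosome 15 (40 to 60 Mb), 0.35 on chromosome 10 (60 to 80 Mb) and 0.39 on the X chromosome (120 to 140 Mb) and of −0.38 at the end of chromosome 20 (beyond 60 Mb) were among the others. When each gene was set against the median of its own bin, 3614 of the 5850 calls kept their direction and passed the threshold, and 381 changed sign.

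**Figure D4:**
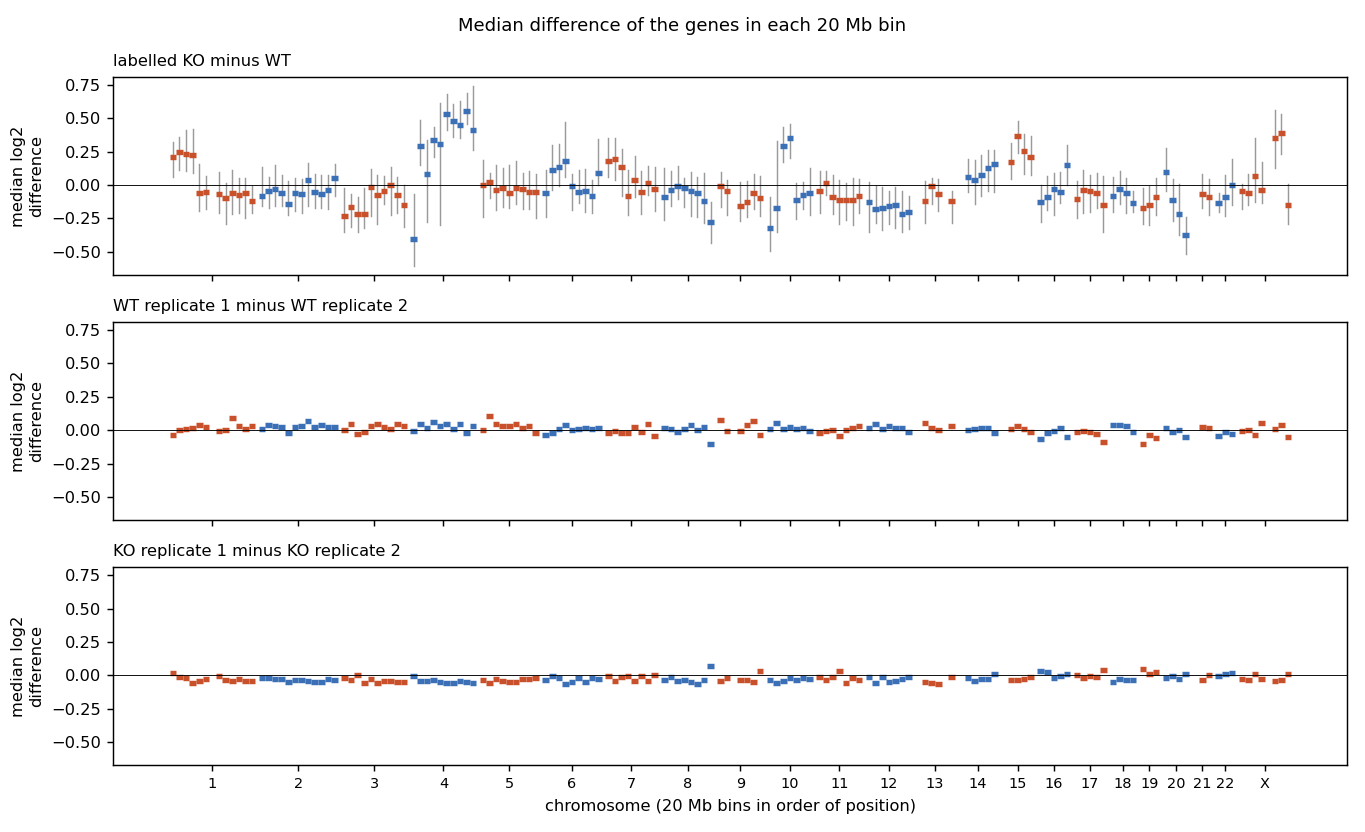
Median log2 difference of the tested genes in each 20 Mb bin along chromosomes 1 to 22 and X, for the libraries labelled KO minus WT (top, with grey lines from the first to the third quartile of the genes), WT replicate 1 minus WT replicate 2 (middle) and KO replicate 1 minus KO replicate 2 (bottom), on the same log2 axis. Bin medians spread with an SD of 0.17 in the top panel and of 0.033 and 0.024 in the lower panels; chromosome 4 runs from −0.40 at its start to 0.55 between 160 and 180 Mb.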

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

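The alternatives with voom, median-of-ratios scaling, no mitochondrial genes, thinning, bin medians, length and GC trends and the crossed block were chosen after seeing the data. The 199 genes described or selected besides RIOX2 gave 3027 values under the alternatives with the same direction and the same side of the threshold, 84 with the same direction but no longer past it, 2 newly past it (both RIOX1) and 5 with the opposite sign; the 16 called lists gave 236, 18, 0 and 0. The 5 opposite signs all came from subtracting bin medians, which by construction removes what a gene shares with its neighbors: NSD2 became 0.00027, CCNA2 −0.011, LAMA5 0.046, GAR1 −0.21 and CT83 −0.056. Genes changed at least 2-fold numbered 149 higher and 154 lower with a pseudocount of 0.1, 209 and 142 with voom, and 50 and 29 with a mean of at least 5 FPKM, which tests fewer genes. The smaller pseudocount and voom shrink low genes less. Voom also used another scaling, and its counts do not separate that from the shrinkage. Leaving out 1 library gave 1542 to 3104 genes higher, 1996 to 3973 lower, 13 to 19 lists called and a RIOX2 change of 0.12 to 0.20. RIOX2 passed the threshold as a rise with a mean of at least 5 FPKM (0.16, adjusted p = 0.0492), quantile normalization (0.17), voom (0.24), median-of-ratios scaling (0.22), bin medians subtracted (0.20), length and GC trends removed (0.12) and without WT replicate 1 (0.19); the cause was not tested, and its adjusted p ranged from 0.00554 to 0.360. Camera with an estimated correlation, a test with few degrees of freedom here, called 0 lists (limma, with 1 at an unadjusted p under 0.05) and fry 20. With the replicate number as a block, 2348 genes were higher and 3029 lower, 18 lists were called, and RIOX2 had an adjusted p of 0.113; among the described genes and called lists, the block ended the calls of PDGFRB and IFIT1 and no other. The deviations of same-numbered libraries correlated at −0.225 across genes, which gave no sign of pairing. With 1 difference per group, trends that span a library can hide pairing, so this value cannot exclude it. A block with the numbers crossed gave 2839 higher and 3821 lower, more of each than the main fit (2527 and 3323). A trend shared by libraries of opposite number was not tested. A gene or list that a filter removed has no value under that filter. The alternatives planned for a count table (a negative binomial test, its size factors and its count filter) were not run because the table holds FPKM. Thinning all libraries to the depth of WT replicate 2 left 2328 genes higher and 3036 lower, with 5176 of the 5837 main calls still tested kept in the same direction.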

Other observations

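The tests of regional shifts against noise between libraries and chance order and by held-out genes, of interferon genes, and of leukocyte genes under 5 FPKM in WT were chosen only after the result was seen, and the other tests of explanations before. Noncoding genes, which the naming rule left out, also changed: of 528 tested long noncoding RNAs, 90 were higher and 188 lower in the libraries labelled KO. The genes in this paragraph, except ITGB2 and SPANXB1, were chosen after their values were seen. CCAT1 (2.42 to 0.484 FPKM), CASC19 (2.43 to 0.361 FPKM) and CASC8 (6.49 to 2.60 FPKM), noncoding genes that neighbor MYC on chromosome 8, fell by 1.20, 1.34 and 1.06 on the log2 scale, and MYC itself fell by 0.34 (31.8 to 24.9 FPKM, adjusted p = 0.00107); their bin had a median of −0.095. UCA1 fell from 17.7 to 6.03 FPKM and KAZN-AS1 by 2.09, while LINC01605 rose by 1.62. AFAP1-AS1 rose by 1.58 (3.43 to 12.2 FPKM) although its bin, at the start of chromosome 4, had a median of −0.40. ITGB2-AS1 fell by 1.23, as did ITGB2 itself, and without a stated strand setting the reads of an antisense gene and of its partner cannot be separated. The cancer-testis list, with 2 members higher and 2 lower of 5 tested (3 and 2 adjusted over the list alone; camera adjusted p = 0.764; median 0.18 but mean −0.13), held MAGEB2 (2.63 to 10.3 FPKM) and CT83 as rises and the SPANX genes SPANXB1 and SPANXC as falls. CT83 was no longer past the threshold with voom (0.41, adjusted p = 0.0515) or without KO replicate 1 (0.26). With bin medians subtracted it changed sign, and over all alternatives its adjusted p ranged from 1.54e-05 to 0.501.

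Other lists moved in both directions, and none of those in this paragraph was called by camera with either correlation, although fry called the lists of the lysosome, serine and one-carbon metabolism, WNT and luminal genes (adjusted p = 0.0266, 0.00848, 0.00810 and 0.0219). In the cell cycle list 10 of 42 rose and 10 fell (10 and 10 adjusted over the list alone; adjusted p = 0.433), with PCNA, the DNA polymerase clamp, rising from 99.9 ± 2.27 to 147 ± 6.54 FPKM, MYBL2 falling by 0.37, and CENPE (0.63) and CCNA2 (0.48) rising in chromosome 4 bins with medians of 0.53 and 0.49, calls lost with bin medians subtracted (0.098 and −0.011). Among p53 targets 9 of 25 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.438): the cell cycle inhibitor CDKN1A rose from 11.4 ± 0.849 to 23.9 ± 1.59 FPKM and the stress cytokine GDF15 fell from 3.88 ± 1.01 to 1.05 ± 0.0480 FPKM. In the lysosome list 11 of 32 rose and 6 fell (12 and 7 adjusted over the list alone; adjusted p = 0.124), led by the protease cathepsin D (CTSD), from 188 ± 7.37 to 504 ± 34.1 FPKM. In serine and one-carbon metabolism 3 of 22 rose and 11 fell (3 and 11 adjusted over the list alone; adjusted p = 0.122), among them PSAT1 (50.5 ± 0.0468 to 31.1 ± 0.546 FPKM) and SHMT2 (−0.45), which the unfolded protein response and ATF4 list also holds; there 5 of 31 rose and 9 fell (5 and 8 adjusted over the list alone; adjusted p = 0.995), with DDIT4 higher by 0.91 (bin median 0.35) and DDIT3 lower by 0.54. WNT ligands and targets split 6 to 6 of 15 (6 and 7 adjusted over the list alone; adjusted p = 0.433; median −0.0018 but mean 0.20), with FZD8 (0.356 ± 0.0242 to 2.36 ± 0.175 FPKM), WNT9A (1.21) and WNT7B (1.14) higher and FZD2 lower by 0.42. YAP and TAZ targets counted 5 higher and 9 lower of 22 (5 and 11 adjusted over the list alone; adjusted p = 0.433), with CRIM1 lower by 0.63 and NT5E higher by 0.51, and immediate early and stress genes 5 and 8 of 25 (5 and 9 adjusted over the list alone; adjusted p = 0.438), with EGR1 lower by 0.55 and FOS higher by 0.51. Fatty acid synthesis counted 5 and 1 of 19 (5 and 1 adjusted over the list alone; adjusted p = 0.0837), with SCD higher by 0.47, and luminal and hormone receptor genes 6 and 3 of 14 (6 and 3 adjusted over the list alone; adjusted p = 0.141), with KRT19 higher by 0.53.

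Smaller or steadier lists gave these counts of higher and lower members. KRAB zinc finger genes, on chromosome 19 except ZNF721 (chromosome 4, −0.49, bin median −0.40) and ZNF140 (chromosome 12), had 9 and 16 of 131 (5 and 8 adjusted over the list alone; adjusted p = 0.863), DNA methylation enzymes 1 and 4 of 10 (1 and 4 adjusted over the list alone; adjusted p = 0.599), and imprinted genes 3 and 3 of 12 (3 and 3 adjusted over the list alone; adjusted p = 0.881; median −0.0087 but mean 0.047). In these, TET2 rose by 0.71 in a chromosome 4 bin with a median of 0.53, TDG fell by 0.32 (bin median −0.21), NAP1L5 rose by 1.14 (bin median 0.27) and PEG10 fell by 0.58. With bin medians subtracted, the calls of ZNF721 (−0.081, limma adjusted p = 0.330), TET2 (0.18, adjusted p = 0.0630) and TDG (−0.11, adjusted p = 0.153) were lost. Clustered protocadherins, whose exons overlap, had 3 and 2 of 8 (3 and 2 adjusted over the list alone; adjusted p = 0.343), neural genes silenced by REST 2 and 3 of 6 (2 and 3 adjusted over the list alone; adjusted p = 0.623, by fry 0.0128), and basal genes 2 and 1 of 5 (2 and 1 adjusted over the list alone; adjusted p = 0.433), with LAMA3 higher by 0.75 and FOXC1 lower by 0.61; these 2, ACTB and the marker genes below except THY1 were chosen after their values were seen. Replication-dependent histone genes had 1 and 1 of 7 (1 and 1 adjusted over the list alone; adjusted p = 0.881; median −0.056 but direction up in camera). The 27 reference genes, chosen as stable in many tissues, had 9 and 6 (9 and 6 adjusted over the list alone; adjusted p = 0.433; median −0.0070 but mean 0.050); ACTB measured 2728 FPKM in WT and 2699 FPKM in the libraries labelled KO. Of the marker lists of other cell types, 4 leukocyte genes were tested, of which LAPTM5 rose (62.1 to 97.0 FPKM) and CD68 (76.8 to 45.4 FPKM), HCLS1 and CORO1A fell. Of 4 endothelial markers ESAM and ROBO4 fell and PECAM1 rose. PECAM1 (0.26) was not past the threshold without KO replicate 1 (adjusted p = 0.0800), without KO replicate 2 (adjusted p = 0.0940) or after thinning (adjusted p = 0.0596), and its adjusted p ranged from 0.000404 to 0.0940. Of 3 stromal markers THY1 fell and COL1A1 (0.37) and PDGFRB (0.19) rose. The call of PDGFRB was lost without WT replicate 2 (adjusted p = 0.101), KO replicate 1 (0.196) or KO replicate 2 (0.215), with no filter (0.0930), with the replicate block (0.0777) and after thinning (0.294), and its lowest adjusted p was 0.00537.

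Regional shifts between the libraries labelled KO and WT were far larger than between libraries of a group: the larger replicate SD of bin medians was 0.196 times that between groups. Shuffling genes over positions gave an SD as large in 0 of 1000 draws (largest 0.054), and removing each library's trend with length and GC content left 0.984 of the SD, which argues against noise, chance and that trend as the cause. In the 15 bins shifted by over 0.3, 89.6% of the genes lay on the side of their bin (61.4% to 100% by bin), a share that the choice of the bins by the same genes makes high; weakly expressed genes there shifted 1.03 times as far as strongly expressed ones (0.50 and 0.48 on the voom scale), which argues against a change of weakly expressed chromatin. A difference in DNA copy number between the cells needs the rest of a region to shift with any part of it. In bins chosen by every second gene, 89.4% of the genes not used for the choice lay on the side of their bin. An example would be a clone with a loss at the start of chromosome 4 and gains in later parts of it. Not every later bin rose as a block: from 20 to 40 Mb the median was 0.29, but from 40 to 60 Mb 19 genes were higher and 15 lower. A copy-number difference may underlie a part of the rises of genes on that chromosome, such as EREG (1.42), AREG (1.32), TENM3 (6.74 to 19.2 FPKM) and UGT8 (1.38). These genes were chosen after their values were seen, and their changes exceeded their bin medians of 0.33 to 0.53. With bin medians subtracted, EREG kept 1.08, AREG 0.98, TENM3 0.99 and UGT8 0.85. Most of each rise was thus not shared with the bin. A copy-number difference stays a hypothesis. A regional change of regulation that moves weakly and strongly expressed genes alike would give the same share, and no DNA data were used here. A copy-number difference and the knockout label also coincide in these 4 libraries.

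MHC class I and II genes rose with a median of 0.58 over 25 tested members, and 0.45 was left after bin medians were subtracted, which argues against the regional shifts as the whole cause. Leukocytes among the cells are a candidate source, and 7 leukocyte genes named in advance did gain 69.4% of the 49.4 FPKM that CD74 gained. This met the bar of at least 5% set beforehand for leukocytes. The gain of the 7 genes came from LAPTM5, already at 62.1 FPKM in WT. A cut at 5 FPKM in WT, chosen after this was seen, leaves LAPTM5 out. The 6 genes under it together changed by −1.09% of the gain of CD74, with PTPRC at 0.139 and 0.134 FPKM. Their values argue against leukocytes. An interferon response cannot be told apart from a change in the MHC genes alone: the 9 tested interferon genes had a median of 0.054, with MX1 (0.36), OAS3 (0.57) and IFI44 (0.53) higher and IFIT1 lower (−0.18, a call lost under 8 alternatives, among them without KO replicate 1, adjusted p = 0.177, and without KO replicate 2, adjusted p = 0.129; range 0.00484 to 0.293), so that members went both ways. An effect of the knockout itself remains open and untested.

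Genes of ribosomes and oxidative phosphorylation were lower in the libraries labelled KO, with medians of −0.22 (ribosome biogenesis), −0.18 (cytosolic ribosomal proteins) and −0.17 (oxidative phosphorylation). Across genes, the change correlated with gene length (Spearman's rho 0.204) and GC content (−0.154), and with those trends removed the ribosomal protein median fell to −0.065, so the trend may account for most of it; the median was −0.13 after bin medians were subtracted and −0.13 without WT replicate 2, which argues against either as the whole cause, although with 1 WT library fewer the list was no longer called (adjusted p = 0.0660). Ribosome biogenesis genes kept −0.18, −0.20 and −0.23 under the same 3 corrections, which argues against each of them as the whole cause. For oxidative phosphorylation, −0.099 and −0.11 with length and GC trends or bin medians removed lie between the bounds set beforehand, so these cannot be told apart from a change of the genes themselves, while −0.15 without WT replicate 2 argues against the shallower library as the whole cause, although the list was no longer called there (adjusted p = 0.0857). An effect of the knockout label on ribosome biogenesis genes is consistent with these values as a hypothesis, as is one of a clone, which the design does not separate from it.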
